A study of Macaca fascicularis and Homo sapiens and Mus musculus with 15 samples.

How the data were processed

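Single-cell RNA was measured in 15 libraries from 3 species: mouse epiblast stem cells of the line 129S2C1a, cynomolgus macaque induced pluripotent stem cells of the line 56A1, and human embryonic stem cells of the line H9. Each species gave 1 untreated library at day 0, in the pluripotent state, and libraries at days 2 and 4 of neural induction with SB431542 and LDN193189, which block nodal and BMP receptors. Days 2 and 4 each had 1 untreated library per species and 1 library treated with 50 nM INK128, an inhibitor of the mTOR kinase. Per the labels' protocols, each sample was marked with a multiplexing oligonucleotide and the samples of a day were pooled over species and treatments. The pool was sorted on light scatter, which left out small particles and clumps, before droplet capture and 3′ library preparation. Day and pool therefore cannot be told apart, while both arms of a day shared a pool. The deposited values are counts of unique molecular identifiers (UMIs) per gene and cell barcode, not normalised, made with Cell Ranger 7.2.0 per the submitters' processing notes. The notes name the builds mm10 and GRCh38, and the build used for cynomolgus reads is not given in the sources used here. The deposited barcodes were already assigned to libraries, and their number equalled the cell number in the labels of each library.

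The gene tables held 32285 mouse, 22323 cynomolgus and 36601 human genes, and 12 oligonucleotide features were left out of library totals and tests. Of the cynomolgus genes, 7203 had an identifier and no symbol. All 3 tables shared 13325 symbols. Mouse and cynomolgus genes were matched to human ones by the same symbol in capital letters, and all genes are given by that symbol. POU5F1, NANOG, SOX1, GYS1 and PGM1 in cynomolgus and GYG1 in mouse, with MSX1 in cynomolgus, were not matched to a symbol and were not analysed here. Cells were kept with at least 1000 UMIs, at least 500 genes and at most 20% of UMIs from mitochondrial genes. No doublet caller was run, and leaving out cells above 2 times the median UMIs of their library was an alternative.

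Counts were summed over the kept cells of a library, which gave between 13908578 and 57800999 gene UMIs, so that 3 UMIs, the limit a count of 0 allows, stood for between 0.0519 and 0.216 CPM, the count of a gene scaled to a common library total. No barcode was shared within the 33 pairs of same-day libraries, and 31 were shared over the 72 pairs from different days, so no library was a copy of another.

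With 1 library per species, day and treatment there was no replicate within a species and no test. Levels there have exact Poisson intervals, ratios of CPM exact conditional binomial intervals and shares of cells exact Clopper-Pearson intervals, all at 95% and all covering counting error only. Ratios of median UMIs have limits made from the 95% order-statistic intervals of the 2 medians, the low end of each over the high end of the other. They reflect the spread between cells of a library and are not themselves 95% intervals. A share of 0 is given with the share that 3 cells of the total would make, a limit that lies below the upper end of the Clopper-Pearson interval. The only replication of the treatment was over the 3 species, with 1 cell line each. P-values of the common tests therefore set an effect against its spread between these species and lines. Common effects were tested with edgeR's quasi-likelihood test, with species as a block, over the 6 libraries of a day for INK128 and over the 9 untreated libraries for time. Differences between species were in the residual spread. Library sizes were scaled with TMM within each species, and genes needed 10 CPM in at least 1 library of each species. Whether the INK128 effect differed between species was tested with an F-test of the species by INK128 terms over the 12 libraries of days 2 and 4, with days standing in for repeats. P-values were adjusted by Benjamini-Hochberg over the genes of a test, with a threshold of 0.05. On counts simulated from the real means with 200 genes drawn to change and a dispersion of 0.02, the test found 99%, 98.9% and 99.0% of genes changed 2-fold for INK128 at day 2, INK128 at day 4 and day 4 against day 0. The share of wrong calls was 4.93%, 1.99% and 2.04% of the calls over 5998, 6036 and 6350 genes, and 100% of genes changed 4-fold were found. Each changed gene was given the same change in all 3 species. The simulated counts thus lacked the differences between species that enter the real residual spread. These shares therefore do not tell how many real changes the test would find.

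The 29 gene lists, fixed before the data were examined, covered pluripotency, neural progenitors, neurons, neural crest and surface ectoderm, mesendoderm, mesenchyme, forebrain and posterior neural identity. Further lists held Notch pathway genes, BMP and nodal targets, glycogen metabolism, glycolysis, the pentose phosphate pathway, ATF4 and amino acid genes, sterol synthesis and fatty acid synthesis. The remaining ones were lysosome and autophagy, translation factors with a terminal oligopyrimidine (TOP) motif, ribosome biogenesis, FOXO and insulin feedback, the mTOR pathway, S phase, G2 and M phase, nuclear genes of oxidative phosphorylation, hypoxia, immediate early and stress genes, p53 and apoptosis, the proteasome and ribosomal proteins. They were tested with limma's camera on log2 CPM with an inter-gene correlation of 0.01, adjusted over the 109 tests of lists in the 4 common comparisons, and again with an estimated correlation. Within a species, genes with 10 CPM or more in at least 1 of 2 libraries were called 2-fold different by the ratio of scaled CPM plus 1. A list's median log2 ratio was set beside 10000 random lists matched on mean expression. For shares of cells with a marker UMI, each cell was thinned to 5000 UMIs and shallower cells were left out. For the position between day 0 and day 4, genes with at least 20 CPM and a log2 ratio of at least 1.5 between those untreated libraries were picked in a random part of their cells, and each library was projected on that difference in the remaining cells, with intervals from 200 Poisson draws.

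The rule for named genes was fixed before the data were examined. It took the 8 genes with the highest and the 8 with the lowest fitted change among those past the threshold with the same sign in all species, or, where no gene passed, the 8 tested genes of the same sign with the largest smallest ratio over the species. It also took the 3 highest and 3 lowest ratios per species and INK128 comparison and the 6 smallest p of the test between species. Up to 4 members of each list were taken by the absolute value of their mean log2 ratio over the species. A fixed set of neural, pluripotency and glycogen genes was added. 1 gene of this fixed set is not reported here. Alternatives were library totals, DESeq2 (with its own size factors over all libraries of a test in place of TMM within species), no filter on low counts, other cell filters, genes of mitochondria and ribosomal proteins left out, other pseudocounts of 0.2 and 5 CPM, a filter at 30 CPM, the mean of CPM per cell, thinning to 2000 UMIs, other gene sets for the position, and leaving out each species in turn. The last of these was added for the test between species after seeing the data. A set of 8 neural crest markers (SOX10, TFAP2A, TFAP2B, PAX3, PAX7, SNAI2, MSX1 and MSX2) was taken from the lists after the results per species were seen and before its own tests. Mitochondrially encoded, X-inactivation and Y-linked genes and symbols that are only an identifier were not named. Versions were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.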

Results

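The series asked how the speed of neural differentiation in mouse, macaque and human cells depends on metabolism, and its mTOR part was measured here in 15 single-cell RNA libraries. Each was 1 combination of species, day and treatment, with no replicate within a species. After filtering, the day 0 libraries held 2039 mouse, 1195 cynomolgus and 1165 human cells, with 32184184, 14028902 and 22773714 gene UMIs. The untreated day 2 libraries held 725, 901 and 664 cells with 15230481, 21605387 and 25485882 UMIs in the same order of species. The day 2 libraries with INK128 held 719, 904 and 626 cells with 17857156, 18277277 and 22452677 UMIs. At day 4 the untreated libraries held 1298, 1215 and 2103 cells with 18949174, 19452992 and 57800999 UMIs. Those with INK128 held 1045, 1416 and 1187 cells with 13908578, 28337207 and 31098755 UMIs.

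The share of barcodes left out by the cell filter differed between libraries, and at day 4 it was higher with INK128 in cynomolgus and human and lower in mouse. In cynomolgus it was 10.4% at day 0, 33.1% without and 46.6% with INK128 at day 2, and 5.15% and 17.6% at day 4. In human it was 12.1% at day 0, 35.8% and 36.7% at day 2, and 7.32% and 16.3% at day 4. In mouse it was 1.64%, then 9.15% and 4.01%, and 5.26% and 1.14%. The median mitochondrial share of these left-out barcodes lay between 23.3% and 90.9%. The label oligonucleotide of a library, taken here as the one with the highest median, was the highest in 44.5% of mouse day 2 INK128 cells and 70.8% of mouse day 0 cells, against at least 98.2% in the other libraries. In those 2 mouse libraries its median was 27.4 and 13.2 times its highest median in the other libraries of its day.

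In untreated cells by day 2, NR2F2 and PAX6 were among the genes that rose most, and DUSP6, SMAD7 and ETV4 among those that fell most. NR2F2, an orphan nuclear receptor of the developing brain, and PAX6, a transcription factor of neural progenitors, had log2 fold changes of 6.37 ± 0.74 (SE, over 3 species) and 4.72 ± 0.76 (adjusted p = 0.0170 and 0.0296, edgeR). GREB1L (5.05 ± 1.15), the secreted BMP modulator SMOC1 (4.40 ± 1.00), the homeobox genes IRX3 (3.92 ± 0.90) and MEIS2 (3.71 ± 0.45), the SMAD-binding repressor ZEB2 (3.78 ± 0.86) and the mitochondrial malic enzyme ME3 (3.66 ± 0.57) rose with them. DUSP6, a phosphatase of ERK, fell by 5.74 on the log2 scale, and the FGF-responsive transcription factor ETV4 (−4.99 ± 0.33) and the inhibitors of receptor tyrosine kinase signalling SPRY4 (−4.80 ± 0.25) and IL17RD (−3.51 ± 0.81) fell with it. SMAD7 (−5.58 ± 0.52) and SKIL (−3.27 ± 0.32), both inhibitors of TGF-beta family signalling, the ion transporter SLC39A8 (−4.35 ± 0.89) and the zinc finger gene BCL11A (−3.45 ± 0.71) completed the lowest values. Of 6708 genes, 498 passed in edgeR, 157 higher and 341 lower, and with library totals the split was 193 higher and 214 lower. The median of all genes was −0.10 on the log2 scale at day 2 and −0.10 at day 4, against 0.01 and 0.07 with library totals, and directions are relative to these. Each day was a pool of its own, so day and pool cannot be told apart. The day 2 count was 31 without mouse, 0 without cynomolgus and 0 without human, where 1556 and 1136 genes had an unadjusted p under 0.05 in edgeR and DESeq2 was not run. With all 3 species DESeq2 gave 1232, and edgeR without a filter on low counts gave 91.

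By day 4, NR2F2 and PAX6 were again among the genes that rose most, and L1TD1 and CDH1 were among those that fell most. NR2F2 rose by 8.94 ± 0.78 and PAX6 by 8.49 ± 0.82 on the log2 scale, followed by LIX1 (5.72 ± 1.34), SMOC1 (5.60 ± 1.06), GREB1L (5.45 ± 1.18), the LIM-only gene LMO1 (4.93 ± 1.42), the transcription cofactor DACH1 (4.81 ± 0.60) and MEIS2 (4.66 ± 0.47). The lowest changes were those of L1TD1, an RNA-binding protein of pluripotent cells (−6.38 ± 1.55), BRINP1 (−5.78 ± 1.29), ETV4 (−5.77 ± 0.34), BCL11A (−5.69 ± 0.80), DUSP6 (−5.46 ± 0.78), the kinase PIM2 (−5.15 ± 1.17), SPRY4 (−5.04 ± 0.26) and CDH1, the E-cadherin of epithelia (−4.97 ± 0.99). Of 6708 genes, 1937 passed in edgeR, 704 higher and 1233 lower, against 1036 and 913 with library totals. Without cynomolgus the count was 0, with 2115 genes at an unadjusted p under 0.05 and DESeq2 not run, and without human it was 4.

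Among the gene lists, that of neural progenitors rose and those of ribosome biogenesis and the proteasome fell over the untreated course. Of 17 neural progenitor genes, 6 rose by day 2 and 10 by day 4, or 9 and 11 adjusted over the list alone, and none fell (camera adjusted p = 2.2e-09 and 3.3e-07). Of 43 ribosome biogenesis genes, 22 and 39 fell, or 36 and 41 adjusted over the list alone, with MYC, a driver of this programme, at −2.62 ± 0.43 and BOP1 at −2.31 ± 0.20 by day 4 (adjusted p = 1.1e-13 and 1.1e-13). Of 29 proteasome genes, 17 and 28 fell, or 27 and 29 adjusted over the list alone (adjusted p = 6.4e-11 and 6.2e-11). The ATF4 and amino acid genes fell too, 5 and 22 of 33, while 1 rose by day 4 (12 and 28 adjusted over the list alone, adjusted p = 7.5e-04 and 7.8e-07), with the amino acid transporter SLC7A5 at −2.58 ± 0.25 by day 4. Sterol synthesis (0.00358 and 0.00310), the pentose phosphate pathway (0.0444 and 0.0213) and S phase (1.6e-04 and 0.0180) fell at both days, with the adjusted p of days 2 and 4 in parentheses. By day 4, 7 of 19, 5 of 6 and 7 of 31 genes of these 3 lists fell, and as many adjusted over the list alone. FOXO and insulin feedback genes rose as a list at both days (adjusted p = 1.6e-04 and 0.0125), 5 of 16 by day 4 while 2 fell. The counts adjusted over the list alone were the same by day 4, with the arrestin TXNIP at 4.14 ± 0.54 and FOXO1 itself at −3.02 ± 0.63. Within cynomolgus the FOXO list had a median log2 ratio of −0.07 by day 4, with 10 of 19 genes below 0. Hypoxia genes rose by day 4, 8 of 16 (9 adjusted over the list alone, adjusted p = 2.0e-04), among them the mTORC1 inhibitor DDIT4 at 2.58 ± 0.72 and the prolyl hydroxylase P4HA1 at 1.94 ± 0.32. BMP and nodal targets fell by day 4, 4 of 9 (5 adjusted over the list alone, adjusted p = 0.0342), as did 14 of 40 nuclear genes of oxidative phosphorylation (16 adjusted over the list alone, adjusted p = 3.3e-04). With an estimated correlation none of these lists passed, with an adjusted p of at least 0.223 in place of each value above.

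Shares of cells with marker UMIs also differed between days, with SIX3, a forebrain gene, seen in more day 4 than day 0 cells in cynomolgus and human and in fewer in mouse. At 5000 UMIs per cell, PAX6 was seen in 47.2% (44.3 to 50.0) of mouse, 44.3% (41.4 to 47.2) of cynomolgus and 24.8% (22.9 to 26.7) of human day 4 cells, against 0.402%, 0% and 0% at day 0, where 0 cells allowed up to 0.278% and 0.266%. SIX3 was seen in 62.8% (60.0 to 65.6) of cynomolgus and 29.1% (27.1 to 31.1) of human day 4 cells, against 0.185% and 0.354% at day 0, and in 6.83% (5.76 to 8.02) of mouse day 0 and 0.491% (0.181 to 1.07) of mouse day 4 cells. POU5F1, the pluripotency factor, was seen in 80.3% (78.5 to 82.0) of mouse and 97.6% (96.5 to 98.4) of human day 0 cells, in 2.70% and 71.2% at day 2, and in 1.56% and 18.9% at day 4. NANOG was seen in 10.6% of mouse and 19.9% of human day 0 cells and in 0.0819% and 0% at day 4, where 0 cells allowed up to 0.145%. Without thinning, the day 4 shares were 74.7%, 75.7% and 65.2% for PAX6 and 1.08%, 83.2% and 70.2% for SIX3, while the day 0 shares of POU5F1 were 86.4% in mouse and 98.4% in human. Median depths before thinning were 14729, 12039 and 19708 UMIs at day 0 and 14112, 15079 and 26457 at day 4. Thinning left out 47, 114 and 36 shallower cells at day 0 and 77, 56 and 34 at day 4.

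With INK128 at day 2, DDIT4, an mTORC1 inhibitor induced by stress, was lower in all 3 species, at a ratio to untreated of 0.284 (0.255 to 0.315) in mouse, 0.333 (0.302 to 0.367) in cynomolgus and 0.0808 (0.0735 to 0.0885) in human. CCN1, a matricellular target of YAP, was higher at 2.64 (2.29 to 3.05) in mouse, 5.87 (5.41 to 6.37) in cynomolgus and 2.98 (2.70 to 3.30) in human. DUSP6 was higher too, at 2.12 (1.75 to 2.57) in mouse, 9.01 (6.96 to 11.8) in cynomolgus and 26.8 (17.9 to 41.7) in human, and the transcription factor NFIB stood at 2.10 in mouse, 4.40 in cynomolgus and 3.16 in human. SMOC1 (0.389 in mouse, 0.441 in cynomolgus and 0.230 in human) and the endocytic adaptor SGIP1 (0.562 in mouse, 0.510 in cynomolgus and 0.191 in human) were lower. PCYT1B, an enzyme of phosphatidylcholine synthesis (2.60 in mouse, 1.98 in cynomolgus and 2.25 in human), and the angiomotin AMOTL2 (1.79 in mouse, 1.87 in cynomolgus and 4.58 in human) were higher. Among the tested genes, which needed 10 CPM in at least 1 library of each species, these 8 had the largest ratio shared in sign by the species, and they are given as a description. In edgeR 0 of 6140 genes passed, with 386 at an unadjusted p under 0.05 and a lowest adjusted p of 0.271, while 68 passed in DESeq2, 44 higher and 24 lower. The fitted log2 change was −2.33 ± 0.41 for DDIT4 and 1.86 ± 0.24 for CCN1, against 2.82 ± 0.64 for DUSP6.

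At the level of gene lists at day 2, those of the translation machinery rose and those of FOXO feedback, p53 and oxidative phosphorylation fell with INK128, by camera with the preset correlation. Ribosomal protein genes rose at a median log2 change of 0.14 over 32 genes (adjusted p = 1.3e-05), and TOP translation factors at 0.15 over 15 (7.6e-05). Ribosome biogenesis rose at 0.14 over 41 (1.1e-04) and the proteasome at 0.08 over 29 (0.00559). Of the mesenchyme list only TAGLN (0.962 in mouse, 5.62 in cynomolgus and 5.03 in human) and VIM (1.56 in mouse, 3.82 in cynomolgus and 3.63 in human), an actin-binding protein and an intermediate filament, could be tested, and this list also passed (adjusted p = 0.00151). Within a species the mesenchyme list had a median log2 ratio of −0.45 in human, and ribosome biogenesis had −0.01 in cynomolgus. VIM is also a member of the TOP list and is abundant in neural progenitors. In mouse neither ribosomal protein nor TOP genes stood above random lists of like expression, with medians of 0.06 and 0.07 at percentiles 4.82 and 44.7, against percentiles 88.8 and 96.8 in cynomolgus and 100 and 99.5 in human. The proteasome median was 0.23 in mouse, 0.03 in cynomolgus and 0.02 in human, at percentiles 100, 69.8 and 30.6. FOXO and insulin feedback genes fell at −0.19 over 14 genes (9.9e-04), with TXNIP at 0.451 in mouse, 0.673 in cynomolgus and 0.456 in human. The others that fell were p53 genes at −0.27 over 9 (6.3e-04), oxidative phosphorylation at −0.08 over 40 (7.4e-04) and fatty acid synthesis at −0.21 over 10 (0.00192). The median mitochondrial share of a cell's UMIs was lower with INK128 in these pairs, at 2.72% against 3.30% in mouse, 2.77% against 3.41% in cynomolgus and 3.43% against 4.88% in human. No member of these 9 lists passed over all genes, and adjusted over the list alone 3 FOXO genes, 2 mesenchyme genes and 1 TOP gene passed and none of the other 6 lists' members. With an estimated correlation the 9 lists had an adjusted p = 0.629 to 0.787.

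**Figure D1:**
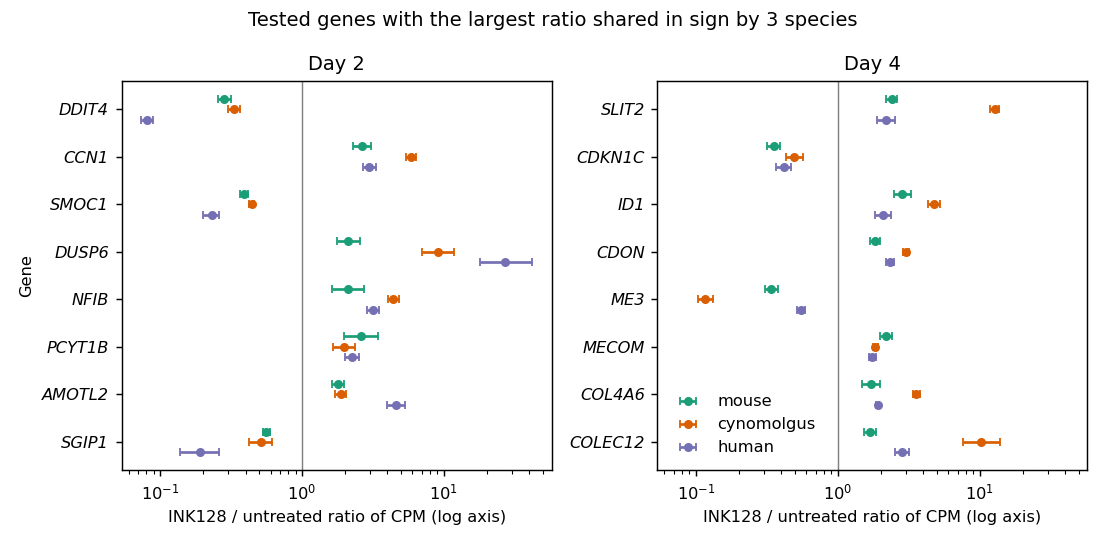
Ratio of CPM with INK128 to CPM without (log axis) for the genes with the largest ratio shared in sign by mouse, cynomolgus and human libraries among those with 10 CPM in at least 1 library of each species, at day 2 (left) and day 4 (right). Points are single pairs of libraries and bars are 95% conditional binomial intervals for counting error only; DDIT4 lies below 1 at day 2 in all 3 species and ID1 above 1 at day 4.

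At day 4, INK128 cells had more ID1, a target of BMP signalling, at a ratio of 2.84 (2.49 to 3.26) in mouse, 4.73 (4.30 to 5.22) in cynomolgus and 2.07 (1.83 to 2.36) in human, and less CDKN1C, an inhibitor of cyclin-dependent kinases, at 0.355 (0.319 to 0.394) in mouse, 0.492 (0.430 to 0.563) in cynomolgus and 0.414 (0.367 to 0.466) in human. SLIT2, a guidance ligand, was at 2.39 in mouse, 12.7 in cynomolgus and 2.19 in human, and the hedgehog co-receptor CDON at 1.83 in mouse, 3.01 in cynomolgus and 2.33 in human. MECOM, a zinc finger transcription factor (2.19 in mouse, 1.84 in cynomolgus and 1.75 in human), the basement membrane collagen COL4A6 (1.71 in mouse, 3.58 in cynomolgus and 1.90 in human) and the scavenger receptor COLEC12 (1.68 in mouse, 10.2 in cynomolgus and 2.84 in human) were higher, and ME3 (0.339 in mouse, 0.116 in cynomolgus and 0.549 in human) was lower. PAX3, a transcription factor of the dorsal neural tube and neural crest named for its list, was at 1.2 (1.16 to 1.25) in mouse, 56.3 (42.9 to 75.2) in cynomolgus and 33.1 (28.6 to 38.6) in human. These are descriptions, since 0 of 6183 genes passed in edgeR, with 501 at an unadjusted p under 0.05, a lowest adjusted p of 0.419, and 60 passing in DESeq2, 39 higher and 21 lower. Without cynomolgus edgeR called 14 genes.

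Gene lists at day 4 again had the translation machinery higher with INK128, and hypoxia genes lower. Ribosomal protein genes rose at a median log2 change of 0.19 (adjusted p = 6.2e-11), 29 of 32 adjusted over the list alone. Ribosome biogenesis rose at 0.23 (3.3e-07, 0 of 42 adjusted over the list alone) and TOP translation factors at 0.15 (2.2e-04, 2 of 15). In cynomolgus the ribosomal protein and TOP lists lay at percentiles 79.1 and 87.7 among random lists. The median mitochondrial share was again lower with INK128, at 2.34% against 2.78% in mouse, 2.18% against 2.55% in cynomolgus and 3.05% against 3.47% in human. Hypoxia genes fell at −0.33 (4.7e-06), 7 of 16 adjusted over the list alone, with DDIT4 at 0.607 in mouse, 0.106 in cynomolgus and 0.0661 in human, the mitophagy receptor BNIP3 at 0.790 in mouse, 0.291 in cynomolgus and 0.247 in human and the glycolytic regulator PFKFB4 at 0.743 in mouse, 0.383 in cynomolgus and 0.281 in human. BMP and nodal targets rose at 0.61 (0.00358), 3 of 6 adjusted over the list alone, with ID2 at 1.53 in mouse, 10.3 in cynomolgus and 1.14 in human and ID3 at 1.26 in mouse, 2.27 in cynomolgus and 1.89 in human beside ID1. ATF4 and amino acid genes rose at 0.18 (0.00405, 0 of 27 adjusted over the list alone) and S phase genes at 0.14 (0.00163, 0 of 29), while G2 and M phase genes fell at −0.13 (0.0126, 0 of 27). Fatty acid synthesis (−0.14, 0.0157, 1 of 10 adjusted over the list alone), neurons (−0.27, 0.0338, 3 of 11) and Notch pathway genes (−0.22, 0.0347, 0 of 9) fell. Mouse did not share the rise of ribosome biogenesis, with a median log2 ratio of −0.11 and 42 of 48 genes below 0 (percentile 4.04 among random lists), or that of ATF4 and amino acid genes, with −0.27 and 31 of 34 below 0 (percentile 0). The S phase median was −0.01 in mouse, that of G2 and M phase 0.09 in cynomolgus, and those of neurons and Notch were 0.04 and 0.07 in human. Neurons and Notch lost the call with library totals (adjusted p = 0.0965 and 0.0912). No member of the 11 lists passed over all genes, and with an estimated correlation they had an adjusted p = 0.629 to 0.807.

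Lists that passed in none of the 4 common comparisons included those of glycogen metabolism and of the mTOR pathway itself. For INK128 at days 2 and 4, camera gave adjusted p = 0.599 and 0.222 for glycogen metabolism, 0.318 and 0.284 for glycolysis, 0.916 and 0.570 for the mTOR pathway. Within mouse at day 2 the glycolysis list had a median log2 ratio of −0.61, with 19 of 22 genes below 0, 8 of them 2-fold lower (percentile 0 among random lists), against 0.11 in cynomolgus and −0.24 in human (percentiles 93.6 and 0). At day 4 its medians were −0.21 in mouse, 0.02 in cynomolgus and −0.40 in human. In the common comparisons camera gave 0.215 and 0.734 for lysosome and autophagy, 0.151 and 0.403 for immediate early and stress genes, and 0.387 and 0.899 for pluripotency. From day 0 to days 2 and 4 it gave 0.490 and 0.0619 for pluripotency, where 6 of 12 genes fell by day 4, and 0.651 and 0.665 for glycogen metabolism. Forebrain and posterior neural lists had at most 2 genes tested and gave 0.0890 and 0.347 for INK128 at day 4, and the neural crest and surface ectoderm list had only PAX3 and EYA1 tested there (0.493). No mesendoderm gene passed the expression filter in all species, and within a species at most 2 of its genes could be measured in any comparison. The median and the mean change had the sign opposite to the camera direction for the mTOR pathway with INK128 at day 2 (median 0.01), for p53 genes at both days of the untreated course (−0.22 and −0.11) and for ribosomal proteins at its day 2 (−0.01). The mean alone had the opposite sign for glycogen metabolism at both days of the untreated course and for immediate early genes with INK128 at day 4. The median alone had it for the pentose phosphate pathway with INK128 at day 2 (0.02) and for neurons (−0.23) and mesenchyme (−0.18) at day 2 of the untreated course.

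Within each species, far fewer genes differed 2-fold with INK128 than over the untreated course. The arms of a day shared a pool, while each day was a pool of its own. The counts over the course may therefore also hold differences between pools. INK128 gave 143 such genes in mouse, 295 in cynomolgus and 464 in human at day 2, and 63, 504 and 266 at day 4. The higher ones numbered 90, 194 and 212 at day 2 and 51, 290 and 147 at day 4. With library totals cynomolgus at day 4 had 254 higher and 288 lower in place of 290 and 214. Untreated cells differed from day 0 in 1904, 1347 and 2303 genes at day 2 and in 2566, 2501 and 3087 at day 4. Of these, 707 were higher in mouse at day 2 and 1032 at day 4, against 1112 higher and 699 lower, and 1642 higher and 911 lower, with library totals. In human at day 2, 1068 were higher and 1235 lower, against 1324 and 893 with library totals.

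In mouse, the highest ratios with INK128 at day 4 were those of the dorsal signalling genes RSPO3 at 25.9 (14.8 to 49.2) and WNT1 at 7.98 (6.0 to 10.8) and of the netrin receptor UNC5C at 5.62 (5.09 to 6.22). The lowest there were those of the peptide gene SST at 0.142 (0.0892 to 0.217) and the smooth muscle genes TAGLN at 0.247 and ACTA2 at 0.292. At day 2 they were LUZP2 (10.2), CNTNAP5B (6.78) and the cadherin CDH6 (5.41) against ANO1 (0.0957), FGF15 (0.145) and RGCC (0.154). In cynomolgus at day 4, PAX3 was among the 3 highest with BMP4, a dorsal signalling ligand at 44.7 (34.1 to 59.8), and the protease PAPPA at 35.0 (28.0 to 44.3). The protocadherin PCDH9 (0.0180), RALYL (0.0256) and the channel gene SCN7A (0.0468) were lowest. At day 2 the secreted SPP1 at 159 (126 to 204), the natriuretic peptide NPPB at 135 (101 to 186) and the actin ACTA1 at 17.2 were highest there, and LMO1 (0.0948), RFTN1 (0.127) and RSPO2 (0.135) lowest. In human at day 4, PAX3 was among the 3 highest with PRRX1, a homeobox gene of mesenchyme, at 18.5 (14.1 to 24.6) and the signalling regulator RGS5 at 15.9 (14.0 to 18.0). DDIT4, the lactate dehydrogenase LDHA at 0.105 (0.0984 to 0.111) and the eye field gene RAX at 0.185 (0.153 to 0.223) were lowest. At day 2 the homeobox gene EMX1 at 41.0 (21.3 to 90.6), DUSP6 and the peptide hormone ADM at 16.4 (12.5 to 21.9) were highest in human, and CDH12 (0.0772), DDIT4 and C11ORF96 (0.114) lowest. These ratios have no replicate check, and their intervals cover counting error only.

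Among the genes for glycogen enzymes given here, the branching enzyme GBE1, the phosphoglucomutase PGM1, GYS1 and UGP2 had ratios under 1 with INK128 at day 4 in each species where they were measured. Those of UGP2 were close to 1. GBE1 was at 0.671 (0.611 to 0.736) in mouse, 0.731 (0.662 to 0.807) in cynomolgus and 0.703 (0.649 to 0.760) in human at day 4, with a fitted log2 change of −0.51 ± 0.10 (adjusted p = 0.452, edgeR) and at 0.873 in mouse, 1.38 in cynomolgus and 0.763 in human at day 2. PGM1 was at 0.447 (0.377 to 0.529) in mouse and 0.496 (0.432 to 0.570) in human at day 2, and at 0.692 (0.624 to 0.767) and 0.421 (0.362 to 0.488) at day 4. The muscle-type glycogen synthase GYS1 was at 1.02 in mouse and 0.573 in human at day 2 and at 0.836 and 0.733 at day 4. At day 4, UGP2, which makes UDP-glucose, was at 0.984 in mouse, 0.992 in cynomolgus and 0.917 in human, and the phosphorylases PYGB at 1.2 in mouse, 0.833 in cynomolgus and 1.01 in human and PYGL at 0.945 in mouse, 1.09 in cynomolgus and 0.722 in human, the last at 2.35 CPM in mouse. Glycogenin GYG1 was at 1.32 in cynomolgus and 0.959 in human. Over the untreated course to day 4, GBE1 was at 2.37 in mouse, 1.16 in cynomolgus and 2.24 in human, UGP2 at 0.896 in mouse, 0.181 in cynomolgus and 0.251 in human and GYG1 at 0.231 in cynomolgus and 0.342 in human, relative to day 0.

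INK128 cells of day 4 also differed in the share of cells with forebrain and dorsal markers. SIX3 was seen in 38.2% (35.6 to 40.9) of cynomolgus and 18.2% (16.1 to 20.6) of human cells with INK128, against the untreated 62.8% and 29.1%. PAX6 was lower in cynomolgus, at 25.4% (23.1 to 27.8) against 44.3%, higher in human, at 34.6% (31.9 to 37.4) against 24.8%, and in mouse the intervals overlapped at 44.4% (41.2 to 47.5) against 47.2% (44.3 to 50.0). PAX3 was seen in 36.2% (33.6 to 38.9) of cynomolgus and 28.3% (25.8 to 31.0) of human cells with INK128, against 1.04% (0.536 to 1.80) and 2.13% (1.55 to 2.84) without. At 2000 UMIs per cell the mouse intervals of PAX6 lay apart, at 21.9% (19.4 to 24.5) against 27.1% (24.7 to 29.6). By CPM the PAX6 ratio of INK128 to untreated was 0.920 in mouse, 0.617 in cynomolgus and 1.47 in human. The mouse share of PAX3 was 72.7% (69.8 to 75.4) against 64.1% (61.4 to 66.8). Day 0 cells, which should lack PAX3, had 0.301% in mouse, 0.185% in cynomolgus and 0% in human, where 0 cells allowed up to 0.266%. The differences between arms in PAX6, SIX3 and PAX3 have no replicate check, and the share of barcodes left out was higher with INK128 in these same cynomolgus and human libraries. Without thinning, SIX3 was at 66.7% and 50.5%, PAX6 at 55.5%, 74.0% and 69.6% in cynomolgus, human and mouse. Unthinned PAX3 was at 62.3% and 52.9% with INK128 against 2.96% and 6.56% without. Median depths with INK128 were 12439, 19592 and 25826 UMIs in mouse, cynomolgus and human. Thinning left out 53, 88 and 19 shallower cells.

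Other markers fixed before the data were examined also differed between arms at day 4, with intervals apart at 5000 UMIs per cell. In cynomolgus SOX2, a transcription factor of pluripotent and neural progenitor cells, was seen in 40.7% (38.0 to 43.4) against 60.4%, DCX, a microtubule protein of young neurons, in 0.527% (0.212 to 1.08) against 5.09% and the proliferation marker MKI67 in 56.3% (53.6 to 59.0) against 48.3% of cells with INK128 and without. In human POU5F1 was seen in 24.1% (21.6 to 26.6) against 18.9% and SOX1, a gene of neural progenitors, in 4.28% (3.19 to 5.61) against 1.79%. In mouse SOX1 was seen in 24.7% (22 to 27.5) against 31.3% and MKI67 in 50.5% (47.3 to 53.7) against 56.5%. At 2000 UMIs the intervals of SOX1 in mouse and human and of MKI67 in mouse overlapped, those of SOX2 in mouse lay apart at 37.1% against 44.2%, and the SOX1 difference in mouse turned from −6.59 to 1.64 points. By CPM the ratios were 0.636, 0.120 and 1.16 for SOX2, DCX and MKI67 in cynomolgus, 1.52 and 2.25 for POU5F1 and SOX1 in human, and 0.851 and 0.961 for SOX1 and MKI67 in mouse. Without thinning the shares were 77.3% against 87.7%, 2.54% against 15.6% and 80.8% against 66.5% in cynomolgus, 70.6% against 59.8% and 17.4% against 9.65% in human and 52.5% against 59.9% and 61.3% against 68.3% in mouse. Day 0 cells had DCX in 0.370% in cynomolgus and SOX1 in 0.177% in human and 11.9% in mouse at 5000 UMIs. No library here was taken to lack SOX2 or MKI67, so their shares have no background value. At day 2 the intervals lay apart for HES5 (11.5% against 22.6%) and PAX6 (23.3% against 16.9%) in mouse, for SIX3 (22.1% against 48.9%), SOX2 (45.3% against 56.7%), MKI67 (27.3% against 40.1%) and PAX6 (1.34% against 3.53%) in cynomolgus, and for MKI67 (22.9% against 15.9%) and SOX1 (1.78% against 7.32%) in human. Of these the intervals overlapped at 2000 UMIs for PAX6 in mouse (10.6% against 7.32%) and cynomolgus (0.336% against 1.01%) and for SOX1 in human (1.28% against 2.27%). Without thinning the day 2 shares were 29.9% against 44.4% and 59.0% against 45.5%, then 44.8% against 81.1%, 76.3% against 89.7%, 47.6% against 68.9% and 4.98% against 10.5%, and 62.6% against 46.1% and 15.2% against 32.4% in the same order. None of these differences has a replicate check.

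**Figure D2:**
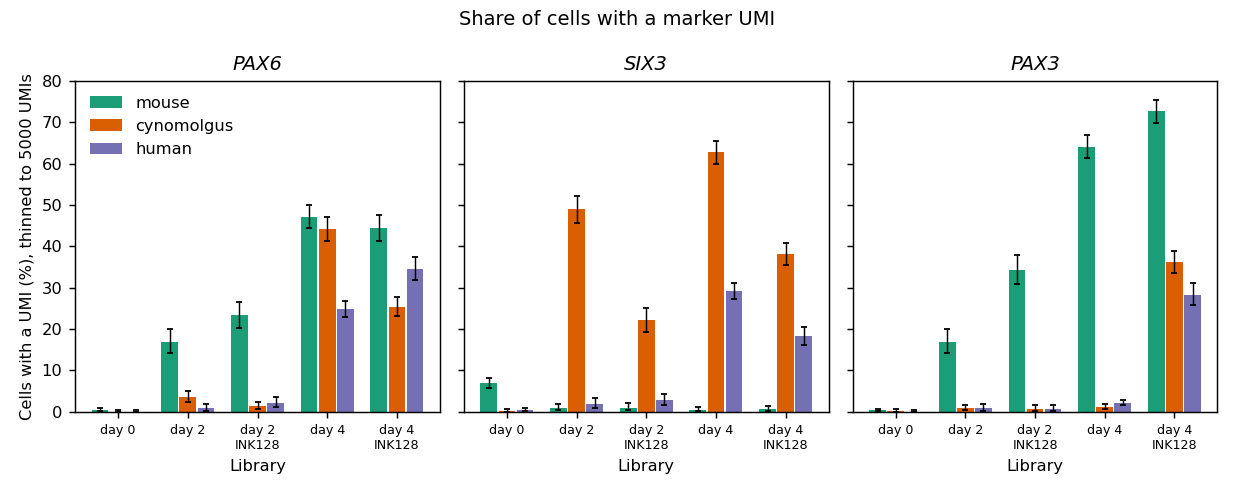
Share of cells (%, starting at 0) with at least 1 UMI of PAX6, SIX3 or PAX3 after thinning each cell to 5000 UMIs, in each of the 15 libraries. Bars are single libraries and error bars 95% Clopper-Pearson intervals; at day 4 PAX3 is at 36.2% in cynomolgus and 28.3% in human cells with INK128.

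Whether INK128 held cells back along the untreated course was described by a position between day 0, set to 0, and untreated day 4, set to 1. It was computed over 940 genes in mouse, 951 in cynomolgus and 1084 in human. The remaining untreated day 4 cells, projected in the same way, stood at 0.998 (0.993 to 1.00) in mouse, 0.978 (0.973 to 0.983) in cynomolgus and 1.00 (0.999 to 1.00) in human. Untreated day 2 cells stood at 0.730 (0.726 to 0.734) in mouse, 0.587 (0.584 to 0.591) in cynomolgus and 0.589 (0.587 to 0.592) in human. With INK128 they stood at 0.753 (0.749 to 0.757), 0.465 (0.462 to 0.469) and 0.495 (0.493 to 0.497), and at day 4 at 0.983 (0.979 to 0.988), 0.792 (0.788 to 0.795) and 0.947 (0.945 to 0.95). The difference from the untreated cells of the same day was −0.122 (−0.125 to −0.119) and −0.186 (−0.190 to −0.182) in cynomolgus at days 2 and 4, −0.0942 (−0.0963 to −0.0921) and −0.0545 (−0.0569 to −0.0522) in human, and 0.0231 (0.0196 to 0.0266) and −0.0145 (−0.0186 to −0.0103) in mouse. The intervals cover counting error only, each difference rests on 1 pair of libraries, and its difference between species was not tested. With only the genes of the pluripotency and neural progenitor lists, the differences at days 2 and 4 were −0.0972 and −0.100 in cynomolgus, −0.0652 and −0.00783 in human and 0.0409 and −0.0232 in mouse. With genes picked at a log2 ratio of 1 or more the mouse differences were 0.0120 and −0.00545, and with a pseudocount of 5 CPM the mouse day 4 difference was −0.00972.

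**Figure D3:**
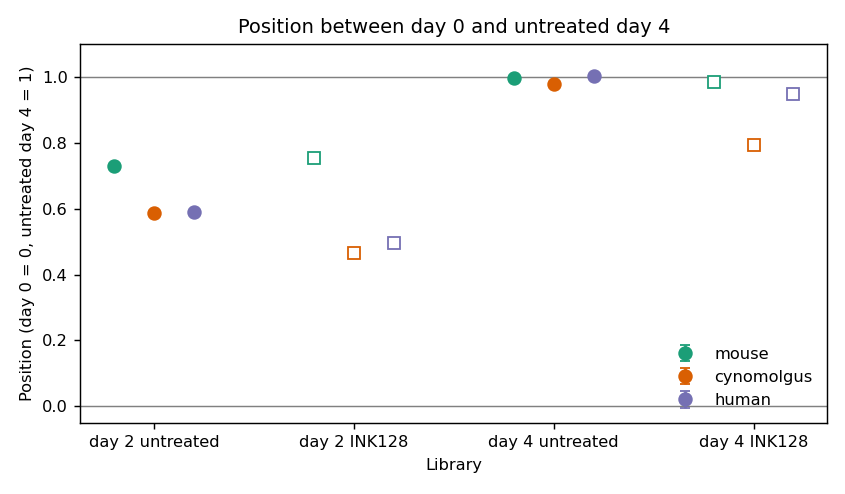
Position of each library between day 0 (0) and untreated day 4 (1) of its own species, without units. Filled circles are untreated and open squares INK128 libraries, each 1 library, with 95% intervals for counting error that are smaller than the symbols; the INK128 squares lie below the untreated circles of the same day in cynomolgus and human.

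UMIs per cell, which follow a cell's RNA content and its capture, were higher with INK128 in mouse at day 2 and cynomolgus at day 4 and lower in mouse at day 4 and cynomolgus at day 2. The ratio of median UMIs with INK128 to untreated was 1.16 (1.09 to 1.24) in mouse, 0.866 (0.802 to 0.917) in cynomolgus and 0.957 (0.907 to 1.02) in human at day 2, and 0.881 (0.838 to 0.933), 1.30 (1.23 to 1.35) and 0.976 (0.929 to 1.02) at day 4. Without the cell filter the cynomolgus day 2 ratio was 0.233.

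The INK128 effect differed between species for 10 genes, and in the 6 with the smallest p the cynomolgus effect was the one that stood apart. LRRC4C, a synaptic ligand, had fitted log2 changes of 0.94 in mouse, −2.33 in cynomolgus and 1.09 in human (adjusted p = 0.00760, edgeR F-test). The tubulin TUBB6 was at −0.30 in mouse, 2.28 in cynomolgus and −0.05 in human and the transporter SLC22A23 at −0.33 in mouse, 1.66 in cynomolgus and −0.45 in human (both adjusted p = 0.0437). KLF6, a zinc finger transcription factor, was at −0.16 in mouse, 1.59 in cynomolgus and −0.40 in human, the actin nucleator COBL at 0.13 in mouse, 1.57 in cynomolgus and −0.35 in human and the cholesterol exporter ABCA1 at 0.37 in mouse, −1.09 in cynomolgus and 0.07 in human (each adjusted p = 0.0471). The remaining calls, named after their values were seen, were PHLDA1, HACD1, FEZ1 and SOBP, out of 6499 genes tested. The count was 6 without mouse, 9 without human and 0 without cynomolgus in edgeR, with 999 genes at an unadjusted p under 0.05 in the last and DESeq2 not run there. With all species it was 189 in DESeq2, 23 without a filter on low counts, 2 without the cell filter, and 1 each without cells above 2 times the median UMIs and without mitochondrial and ribosomal protein genes.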

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

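The tests of other splits of the libraries, the test of low-quality cells for differences between species, the comparison of depth with the ID1 ratio, and leaving out each species in the test between species were chosen after the result was seen, and the other tests before.

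Some lists had a median at least 1.5-fold higher in 1 species and at least 1.5-fold lower in another, a limit chosen during the analysis, and the difference was not tested. Their medians are given as log2 ratios. The mesenchyme list had a median of 0.81 in cynomolgus and −0.88 in mouse with INK128 at day 4. From day 0 to day 2 in untreated cells it had 0.84 in cynomolgus and −0.70 in mouse, and to day 4 0.73 in mouse, 0.66 in cynomolgus and −0.98 in human. The forebrain list had 4.58 in cynomolgus, 3.14 in human and −1.53 in mouse at day 2, and 3.93, 4.15 and −3.54 at day 4. The neural crest and surface ectoderm list had 3.84 in mouse, −2.54 in cynomolgus and −1.65 in human at day 4. Each of these medians covers between 4 and 8 genes.

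Oligonucleotides that labelled no library of a day still gave UMIs in its cells. The lowest median per cell over the libraries of days 0, 2 and 4 was 6, 14 and 56 UMIs for CMO304 and 8, 35 and 64 for CMO305, and on days 2 and 4 it was 20 and 69 for CMO309. CMO310, CMO311 and CMO312 had a median of 0 in each library.

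INK128 cells stood behind untreated cells on the untreated course in cynomolgus and human, at both days. The lower and upper quartiles of a score per cell both moved, at a smallest ratio of 0.679, so a small group of lagging cells does not account for the whole difference. Low-quality cells stay open: with the stricter cell filter each difference kept at least 0.988 of its size, but over whole libraries the cynomolgus day 2 difference was −0.123 with the cell filter and −0.122 with none, so this test could hardly move it, and the share of barcodes left out was higher with INK128 in cynomolgus at both days and in human at day 4. A slower course may be 1 explanation, and a change of regional identity, with more PAX3 and less SIX3, could lower the position as well. They were not tested apart, there was no replicate, and with genes of the pluripotency and neural progenitor lists only, the human day 4 difference was −0.00783 in place of −0.0545.

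ID1 was higher with INK128 in all 6 pairs. At 5000 UMIs per cell the share of cells with ID1 was higher with intervals apart in 5 of the 6 pairs. Depth does not account for the higher share in these 5. In human at day 2 the intervals overlapped, at 8.56% (6.48 to 11.1) against 5.95% (4.26 to 8.04), so the thinned shares do not decide there. INK128 cells were not deeper in that pair, with a ratio of median UMIs of 0.957 and an upper bound of 1.02. The ID1 ratio of 1.75 (1.53 to 2.01) was already scaled to library size, so setting it against this ratio does not test depth. Without cells holding a neural crest marker UMI, the ID1 ratios were 2.31, 4.03, 2.78, 4.92, 1.68 and 1.83 for days 2 and 4 of mouse, cynomolgus and human. At day 2 this removed 16.6% of cynomolgus cells with INK128 and 17.2% without, and 13.6% and 19.6% of human cells. At 5000 UMIs per cell the intervals of these shares overlapped. The ID1 ratio there was 2.86 and 1.75 with all cells, so it was also higher among cells without a marker UMI. The filter acted at full depth and took out only cells in which a marker was detected. It therefore does not decide, and cells of this type stay open as a source in all 6 pairs. In mouse and at day 4 a larger share was removed with INK128, such as 75.8% against 9.55% in cynomolgus at day 4. Unmarked cells of the same type may also remain among the shallower ones (9068 against 12724 UMIs in mouse and 24164 against 27166 in human at day 4 with INK128). ID1 also fell over the untreated course, from 19.6% of mouse, 16.4% of cynomolgus and 25.2% of human cells at day 0 to 7.13%, 10.0% and 3.67% at day 4. With INK128 the shares at days 2 and 4 were 21.3% and 14.9% in mouse, 20.7% and 38.5% in cynomolgus and 8.56% and 6.16% in human. The human shares thus lay between day 0 and untreated cells, and the cynomolgus day 4 share lay above day 0. A slower course or a weaker block of BMP signalling may be behind the higher ID1, and neither was tested.

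The test between species called 10 genes, with adjusted p (edgeR) of 0.00760 for LRRC4C, 0.0437 for SLC22A23 and TUBB6, and 0.0471 for KLF6, COBL and ABCA1. The median distance of the cynomolgus effect from the mean of the other species over these genes was 1.01 times its size with the stricter cell filter and 1.03 times without cells holding a neural crest marker UMI. Neither test decides, since the distance was 1.66 on the log2 scale with the cell filter and 1.62 with none, and the marker filter followed INK128 itself, so both kinds of cell stay open. Species and cell line cannot be separated here, with 1 line each, and a difference between species could not be told from a difference between lines. Of 15 ways to group the libraries, 1 gave as many genes, the real grouping, and the highest other gave 4, and 15 groupings are too few for a share under 0.05.

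Splits of the 6 libraries of a common comparison number 10, too few for a share under 0.05. For INK128 at days 2 and 4 the real split gave 0 genes, a count that every split reaches, so that 10 of 10 and 10 of 10 gave as many by construction and decide nothing. The highest other split gave 0 at day 2 and 79 at day 4, the latter in 2 splits that part the pair of only 1 species. With species as a block these 2 test the same contrast, the single pair of that species, which the 79 genes describe. From day 0 to day 2 the real split gave 498 and the highest other 0, and to day 4 1937 and 0, with 1 split of 10 as large in each.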

How the results depend on the processing

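Leaving out each species in turn in the test between species was chosen after seeing the data, and the other alternatives before. At 2000 UMIs per cell the mouse day 4 difference in the share of cells with SOX1 turned from −6.59 to 1.64 points, with overlapping intervals. With library totals more genes were higher than lower, and not the reverse, in the common change to day 4, in mouse and human at both days and in cynomolgus at day 4 against day 0, and more were lower in cynomolgus at day 2 against day 0 and with INK128 at day 4. No named gene called in a common comparison, difference in position or ratio of UMIs changed its sign under these alternatives. The other called genes were not checked for this. In mouse the medians of the score per cell, which is not among the alternatives, went the other way from the differences in position. Of the alternatives, 12292 of 13074 values of named genes in the tests and 174 of 218 list calls stayed on their side of the threshold. Of named genes in a species, 627 of 756 values stayed within the main interval, as did 20 of 48 positions. Within 1.5 times the main count stayed 82 of 108 2-fold counts and 38 of 55 test counts. For marker shares, 68 of 120 differences between arms moved by no more than a margin set by the wider interval of the arms. Of the named genes in tests, 593 lost and 189 gained the threshold, and of the list calls 41 and 3. With DESeq2 the tests called 68 genes for INK128 at day 2, 60 at day 4, 1232 from day 0 to day 2 and 189 between species. Without a filter on low counts they called 91 from day 0 to day 2 and 23 between species, where no cell filter gave 2, and leaving out cells above 2 times the median UMIs, or mitochondrial and ribosomal protein genes, gave 1 each. Leave-one-out ranges were 0 to 0 and 0 to 14 for INK128 at days 2 and 4, 0 to 31 and 0 to 1502 for days 2 and 4 against day 0, and 0 to 9 between species. With an estimated correlation 0 lists passed in each of the 4 common comparisons. The 2-fold counts without a filter on low values were 397 and 271 in mouse, 483 and 813 in cynomolgus and 825 and 490 in human with INK128 at days 2 and 4, and against day 0 3032 and 3994 in mouse, 2060 in cynomolgus at day 2, and 3574 and 4705 in human. At 30 CPM they were 69, 22, 1214 and 1704 in mouse, 164, 289, 813 and 1657 in cynomolgus and 245, 135, 1346 and 1929 in human in the same order. With a pseudocount of 5 CPM they were 83 and 36 in mouse with INK128 at days 2 and 4 and 175 in human at day 4. Without the cell filter the ratio of median UMIs in cynomolgus was 0.233 and 1.18 at days 2 and 4. Position differences between arms with genes of a log2 ratio of 1 or more were 0.0120 and −0.00545 in mouse, −0.110 and −0.195 in cynomolgus and, at day 4, −0.0604 in human. With a pseudocount of 5 CPM the mouse day 4 difference was −0.00972. With the pluripotency and neural progenitor lists they were 0.0409 and −0.0232 in mouse, −0.0972 and −0.100 in cynomolgus and −0.0652 and −0.00783 in human. The cause was not tested. Depth limits genes of few UMIs most, and intervals cover counting error only, or for median UMIs the spread between cells of a library.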

Other observations

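BMP4, a roof plate ligand, was at a ratio of INK128 to untreated CPM of 2.80 in mouse, 2.01 in cynomolgus and 2.53 in human at day 2 and 2.51 in mouse, 44.7 in cynomolgus and 3.46 in human at day 4. It and the genes that follow were chosen after their values were seen, and were not tested as a group. RSPO3, which potentiates WNT signalling, was at 25.9 in mouse, 4.32 in cynomolgus and 5.43 in human at day 4, and WNT1 was at 7.98 in mouse, 6.02 in human and at least 5.94-fold higher in cynomolgus, where untreated cells held 0 UMIs and 3 were taken as the floor. At day 2, RSPO3 was at 8.02 (3.20 to 25.9) in mouse and 1.57 (0.636 to 4.00) in cynomolgus, and WNT1 at 0.972 (0.812 to 1.16) and 0.161 (0.0179 to 0.693), while the human libraries held at most 2 UMIs of either gene. Levels with INK128 at day 4 were low in part, with BMP4 at 4.37 CPM in mouse, 115 in cynomolgus and 16.4 in human, RSPO3 at 16.7, 10.5 and 3.58, and WNT1 at 22.3 in mouse and 4.17 in human. RAX, a gene of the eye field, was at 0.116 in cynomolgus and 0.185 in human, and SIX3 at 0.464 and 0.626. At 5000 UMIs per cell, PAX7, a dorsal transcription factor, was seen in 21.0% (18.8 to 23.3) of cynomolgus day 4 cells with INK128 and 0.777% (0.356 to 1.47) without. The PAX7 intervals overlapped in human, at 1.37% (0.785 to 2.22) and 0.628% (0.335 to 1.07), and in mouse, at 34.9% (31.9 to 37.9) and 31.2% (28.6 to 33.9). In mouse, PAX3 was already at 34.3% (30.8 to 38.0) with and 16.9% (14.2 to 19.9) without INK128 at day 2. SOX10, which marks migrating neural crest, was seen in at most 2.37% of the cells of any library at this depth, and TFAP2A in at most 1.11%. Without thinning SOX10 reached 12.5% and 11.5% of untreated human cells at days 2 and 4, against 5.75% and 4.80% with INK128, at median depths of 38222 and 26457 UMIs untreated, and TFAP2A at most 1.98%.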
